A study of Mus musculus with 66 samples.

How the data were processed

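Bulk RNA sequencing was used to measure gene expression in 3 brain regions of C57bl6 mice after chronic social defeat, a stress protocol in which a mouse is repeatedly defeated by an aggressor. Per the labels, defeat lasted 10 days, and the Modified Social Interaction test then divided the defeated mice into Indiscriminate-avoiders, Discriminating-avoiders and Non-avoiders beside an undefeated Control group. The regions were the medial prefrontal cortex (mPFC), the basolateral amygdala (blA) and the ventral hippocampus (vHC). Tissue was punched from frozen brain sections, and RNA was extracted with a column kit for small samples. Per the labels' protocols, complementary DNA was made from a sub-nanogram amount of total RNA with a template-switching kit for low input, libraries were tagmented, and single reads were sequenced on a NextSeq instrument. PCR reads without molecular identifiers are not independent molecules, so limits drawn from a count of 0 cover counting error only.

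The deposited values are raw read counts per gene, 1 file per library. The authors aligned reads with STAR 2.5.3a and counted them with featureCounts of Subread 1.5.3, after FastQC 0.11.8, per the submitters' processing notes. Per the file headers, the deposited counts are of exons grouped by gene in GENCODE M17 without regard to strand, and a read that overlaps several genes was counted for each. Reads of overlapping genes, and of genes on opposite strands at one place, therefore cannot be told apart, and reads of near-identical copies such as Hba-a1 and Hba-a2 or Hbb-bs and Hbb-bt are uncertain for each copy. Coordinates are those of the count files, on GRCm38 (mm10), 1-based, from the first to the last annotated exon base. Gene symbols were matched by identifier for 53620 of 53801 genes.

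The 66 libraries came from 28 animals by the animal codes in the labels, of which 13 gave 3 regions, 12 gave 2 and 3 gave 1. Animal codes recur with different phenotypes in the library numbers s14 to s54 and s64 to s105, so these ranges were taken as 2 sets of animals, called set 1 and set 2. The file headers also name 2 sequencing pools. In the vHC all 6 Control libraries were in pool 1, and in the blA and the mPFC all Non-avoider libraries were in pool 2, so pool and phenotype are partly confounded. The blA library s26 is labelled Discriminating-avoiders, while the libraries of its animal code from the other regions are labelled Non-avoiders. It was kept under its own label. In the test of whether changes differed between regions it was given an animal block of its own, and in region against region it stayed in the block of its animal code. No pair of libraries of a group differed by as little as sampling noise. The chi-square per degree of freedom over genes with at least 10 reads lay between 26.6 and 454.

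Each region was fitted alone with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr with its default minimum, quasi-likelihood fits with robust spread, all 4 phenotypes together, and library set as a term. The filter kept 22573 genes in the blA, 22184 in the vHC and 21946 in the mPFC. There were 7 comparisons per region and 21 in all. Genes past a Benjamini-Hochberg adjusted p of 0.05 are said to have risen or fallen. Among genes that do not change, an exact test gives an unadjusted p under 0.05 to a share of 0.05. CPM are counts scaled by the TMM-adjusted library size, and fold changes are log2 with standard errors (SE). The 3 regions were also fitted together over 24721 genes with the animal as a block. Region against region was tested for a fold above 2 (glmTreat) in a model without phenotype. In a separate model with terms for phenotype within region, a quasi-likelihood F-test asked whether a phenotype's change from Control differed between regions.

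A total of 34 gene lists with 460 genes were written down before the data were examined, as were the groups, tests, main models and most alternatives. The lists name cell types (pan-neuronal, glutamatergic, GABAergic and striatal-type neurons, astrocytes, oligodendrocytes and their precursors, microglia, endothelial and mural cells, meningeal fibroblasts, choroid plexus, ependyma, erythrocytes, immature neurons), regions (hippocampus, basolateral and central amygdala, frontal cortex) and programmes (glucocorticoid response, immediate early genes, heat shock, circadian output, inflammation and interferon, glutamate receptors and postsynapse, GABA-A receptors, monoamine receptors, neuropeptides, neurotrophins, nuclear and mitochondrial respiratory chain genes, ribosomal proteins, cholesterol synthesis, perineuronal nets). They were tested with fry in limma 3.58.1, whose p tests whether the genes of a list move, on balance, one way, over 238 tests per region. Neither this p nor its mixed form compares a list with other genes. The competitive test camera was run beside it with a preset correlation of 0.01 and with an estimated one. A list's level in a library is the mean of log2(CPM + 1) over its genes that passed the filter of that region. Filter and scaling were made in each region alone, so levels of different regions can average different genes and are not strictly comparable. Levels of groups within a region were compared by exact two-sided permutation tests, adjusted over 612 tests.

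Named genes follow a rule: of genes past the threshold with a mean log2 CPM of at least 1, the 10 with the smallest p in each direction, and all list members past the threshold. Where no gene passed, the 3 genes with the smallest p are given as values, except that some genes are not reported here. Fkbp5, Sgk1, Tsc22d3, Fos, Arc, Npas4, Bdnf, Crh, Nr3c1 and Ttr were always read out. Ms4a6c and Slc17a7 lie outside this rule and were chosen after their values were seen.

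Alternatives were DESeq2 1.42.0, limma-voom with sample quality weights, RLE size factors, no low-count filter, no set term, each set alone, each library left out in turn, and library s26 left out or counted with the Non-avoiders. For the regions they were Control libraries only and limma-voom with the animal as a random effect. Chosen after seeing the data were a pool term, leaving out the 5 libraries with fewer than 20000 genes, the number of detected genes as a term, a stricter filter (mean log2 CPM of at least 3), a correction of each library for its trend with transcript GC content and exonic length, and scaling by total counts for the erythrocyte level. The tests by edgeR, DESeq2, limma-voom with sample quality weights and fry were first run on simulated counts for the real genes and library sizes. So were the agreement of sets, the F-test between regions and glmTreat between vHC and mPFC. Camera, the permutation tests of list levels and of correlations between regions, limma-voom with the animal as a random effect and the correction for GC content and length were not simulated. With 100 genes changed 4-fold between Indiscriminate-avoiders and Controls, edgeR recovered 59% of them in the blA, 74% in the vHC and 56% in the mPFC, and of 100 genes changed 2-fold it recovered 20%, 42% and 3%. Of the unchanged genes edgeR called 2, 4 and 2, limma-voom called 3, 6 and 4, and DESeq2 called 56, 40 and 107 in the blA, vHC and mPFC. The simulations of the region models used 3000 genes and no animal effect. In them the F-test recovered 56% of genes whose change differed 4-fold, and glmTreat recovered 83% of genes changed 4-fold. Fry called 4 of 4 changed lists and 0 of 30 unchanged lists in each region. In the changed lists every gene changed 2- or 4-fold, all genes were drawn independently of each other, and fewer than 238 tests were adjusted for. The power of fry for real lists, whose genes may vary together between libraries, was therefore not measured. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 was used for permutation tests.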

Results

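Gene expression was measured by RNA sequencing in 66 libraries of mouse brain tissue after chronic social defeat. The series asks whether the phenotypes that defeated mice show in a social interaction test have transcriptional signatures that differ between brain regions. The blA was represented by 22 libraries (5 Control, 6 Indiscriminate-avoiders, 7 Discriminating-avoiders, 4 Non-avoiders), the vHC by 25 libraries (6, 7, 5 and 7 in the same order) and the mPFC by 19 libraries (4, 6, 4 and 5). Total counts per library ranged from 23716790 to 37574984, with a median of 28427383. Between 16021 and 27178 of the 53801 genes had a count in a library. In the blA the number of genes with a count averaged 22093 in Controls, 24579 in Discriminating-avoiders (exact permutation p 0.0227, adjusted p 0.571) and 25569 in Non-avoiders (exact permutation p 0.0238, adjusted p 0.571), and the 4 Non-avoiders (24661 to 26594) lay above the 5 Controls (18736 to 24351). Indiscriminate-avoiders averaged 22986, below Non-avoiders at an exact permutation p of 0.0238 (adjusted p 0.571) and below Discriminating-avoiders at one of 0.035 (adjusted p 0.629).

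The regions differed from each other in marker genes, among them those of other tissues, such as choroid plexus in the vHC and striatal-type neurons in the blA. These tests used all libraries, the animal as a block and a minimum fold of 2, so their counts are not comparable with those of the phenotypes. Myelin genes were higher in the vHC than in the mPFC in 12 of 12 list members, with a median log2 fold change of 3.62. Mbp, a structural protein of myelin, stood at 14190 ± 11700 CPM (SD, n = 25) in the vHC and 562.5 ± 235 CPM (n = 19) in the mPFC. Choroid plexus genes were higher in the vHC in 9 of 11 members, among them Ttr, the thyroxine carrier of the cerebrospinal fluid (3230 ± 3540 against 9.71 ± 17.1 CPM), and hippocampal genes in 6 of 12, among them the transcription factor Zbtb20 (log2 fold change 1.77 ± 0.164 SE). Immediate early genes, which neurons switch on with activity, were lower in the vHC in 7 of 20 members and higher in 0, with Fos at 21.3 ± 8.26 against 83.4 ± 38.5 CPM. The neuropeptide Vip was also lower (30.4 ± 22.8 against 246.5 ± 65.4 CPM).

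In all, 1690 genes differed by more than 2-fold between vHC and mPFC (1287 higher in the vHC, 403 lower) at an adjusted p of 0.05 by edgeR's glmTreat. Adjusted over the list alone, 12 myelin, 9 choroid plexus and 9 hippocampal genes were higher in the vHC, and of immediate early genes 13 were lower and 1 higher. In the other lists the numbers higher and lower over all genes were 4 and 0 of 8 for ependyma (6 and 0 adjusted over the list alone), 5 and 0 of 15 for monoamine receptors (5 and 1), 4 and 2 of 25 for neuropeptides (9 and 4), 2 and 0 of 8 for the basolateral amygdala (3 and 0) and 2 and 0 of 8 for the central amygdala (3 and 1). For the following lists the counts adjusted over the list alone equalled those over all genes. They were 0 and 2 for glutamatergic neurons and for the frontal cortex, 2 and 2 for GABAergic interneurons, 2 and 1 for immature neurons, 2 and 0 for neurotrophins, 1 and 2 for glutamate receptors, 0 and 1 for glucocorticoid-responsive genes, 1 and 1 for GABA-A receptors and for striatal-type neurons, and 1 and 0 for astrocytes, oligodendrocyte precursors, cholesterol synthesis and perineuronal nets. No gene passed either way among pan-neuronal, microglial, endothelial, mural, meningeal fibroblast, erythrocyte, heat shock, circadian, inflammatory, nuclear respiratory chain, mitochondrially encoded and ribosomal protein genes. With Control libraries only, 82 genes passed.

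The blA differed from the mPFC in striatal-type and amygdala genes, among others. Striatal-type genes were higher in 6 of 12 members (11 adjusted over the list alone), among them the opioid precursor Penk (1946 ± 1600 CPM, SD, n = 22, against 134 ± 51.5, n = 19) and the dopamine receptor Drd1 (80.4 ± 90.8 against 3.79 ± 4.67 CPM). Myelin genes were higher in 12 of 12 members (12 adjusted over the list alone), with a median log2 fold change of 2.34, and basolateral amygdala genes in 5 of 8, with 1 lower (5 and 1 adjusted over the list alone). Glutamatergic genes were lower in 5 of 9 members (7 lower and 1 higher adjusted over the list alone) and immediate early genes in 7 of 20 (9 adjusted over the list alone). Arc stood at 59.7 ± 26 against 225 ± 117 CPM. Frontal cortex genes were higher in the blA in 2 of 12 members and lower in 0 (3 and 2 adjusted over the list alone, median 0.494). The list level was 4.52 ± 0.336 in the blA and 4.07 ± 0.329 in the mPFC, each over the members that passed its own region's filter. Neuropeptide genes were higher in 8 and lower in 3 of 25 members (12 and 4), and monoamine receptors higher in 5 of 15 (6). The test called 1002 genes (665 higher in the blA, 337 lower), and 12 with Control libraries only.

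Between vHC and blA, 488 genes differed by more than 2-fold (370 higher in the vHC, 118 lower), and 5 with Control libraries only. Choroid plexus genes were higher in the vHC in 7 of 11 members (9 adjusted over the list alone), ependymal genes in 5 of 8 (6) and hippocampal genes in 3 of 12 (9). Striatal-type genes were lower in 5 of 12 members (10 adjusted over the list alone), neuropeptides in 6 of 25 (7), monoamine receptors in 3 of 15 (3) and frontal cortex genes in 1 of 12 (3). Gfap, an intermediate filament of astrocytes, was higher in the vHC (956 ± 398 against 116 ± 72.7 CPM, SD, n = 25 and 22), and Crh, the corticotropin-releasing hormone, was lower (5.96 ± 3.13 against 20.9 ± 12.1 CPM). No myelin gene passed, although the median log2 fold change of that list was 1.29.

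**Figure D1:**
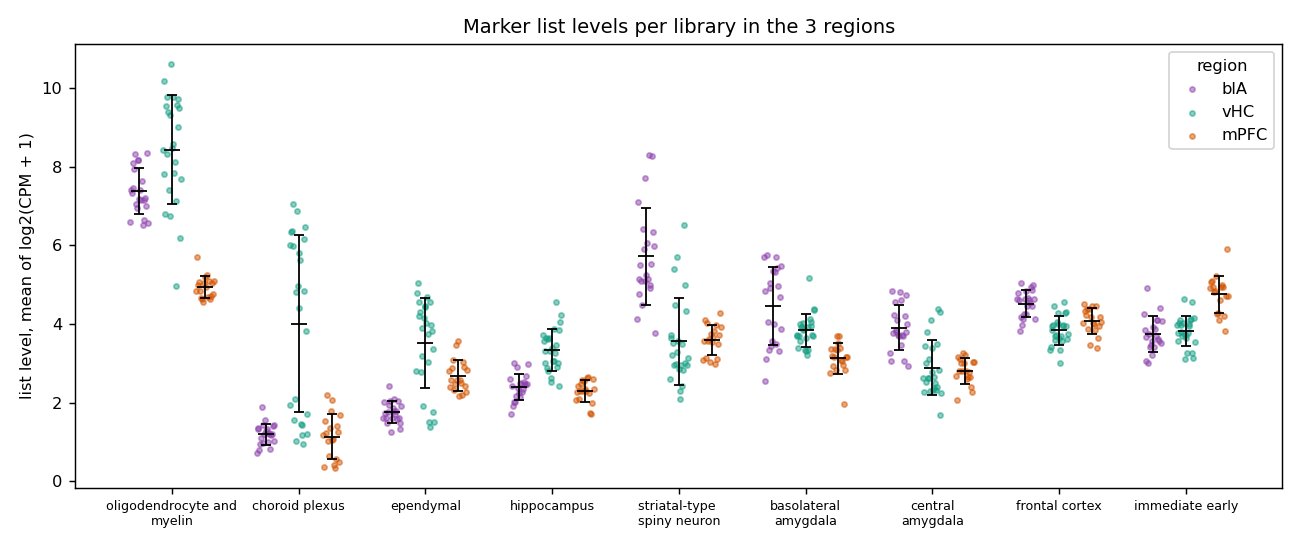
Level of 9 marker lists per library, as the mean of log2(CPM + 1) over the genes of the list that passed the filter of the region, in blA (n = 22), vHC (n = 25) and mPFC (n = 19), with points for libraries and bars for the mean and SD. The genes averaged can differ between regions. Choroid plexus levels in the vHC spread from 0.956 to 7.04.

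Indiscriminate-avoiders differed from Controls in the blA in 6 genes. Zdhhc8, a palmitoyltransferase (chromosome 16, 18220754 to 18235136), stood at 4.23 ± 1.27 CPM (SD, n = 6) against 18.9 ± 8.33 CPM (n = 5) and fell by 2.21 ± 0.363 (SE) on the log2 scale. Amigo1, a neuronal adhesion protein (chromosome 3, 108186335 to 108192286), stood at 8.96 ± 3.17 against 31 ± 10.7 CPM. Aatk, a kinase of the nervous system (chromosome 11, 120007313 to 120047167), stood at 20.7 ± 10.1 against 64.8 ± 36.9 CPM. Leng8 (chromosome 7, 4137039 to 4148177) stood at 18.4 ± 6.46 against 49.5 ± 12.7 CPM, and the kinase Mast2 (chromosome 4, 116306762 to 116464183) at 15 ± 3.82 against 38.5 ± 9.96 CPM. These 5 genes fell at an adjusted p of 0.0413 each by edgeR's quasi-likelihood test and lay below the Control mean in 6 of 6 libraries, and the other gene, Ms4a6c, rose.

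Beside these 6 genes, 3251 had an unadjusted p under 0.05, and DESeq2 called 825 (288 higher, 537 lower) and limma-voom 34. The count depended on single libraries: it was 301 (40 higher, 261 lower) without Control library s98, 19 without Control library s50, 15 without Non-avoiders library s74 and 11 without Non-avoiders library s83. It was 4 without Indiscriminate-avoiders library s38, 3 without library s86, and 2 without Control library s101 or Discriminating-avoiders library s17. It was 1 without Control library s47, Indiscriminate-avoiders library s35, s41, s89 or s92, Discriminating-avoiders library s14, s23, s26, s68 or s71, or Non-avoiders library s32 or s77. It was also 1 with no set term, with a pool term or with detected genes as a term, and 3 (2 higher, 1 lower) with each library corrected for its trend with transcript GC content and length. By edgeR 0 genes passed in set 1 alone and in set 2 alone, where each of these groups holds 2 or 3 libraries.

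**Figure D2:**
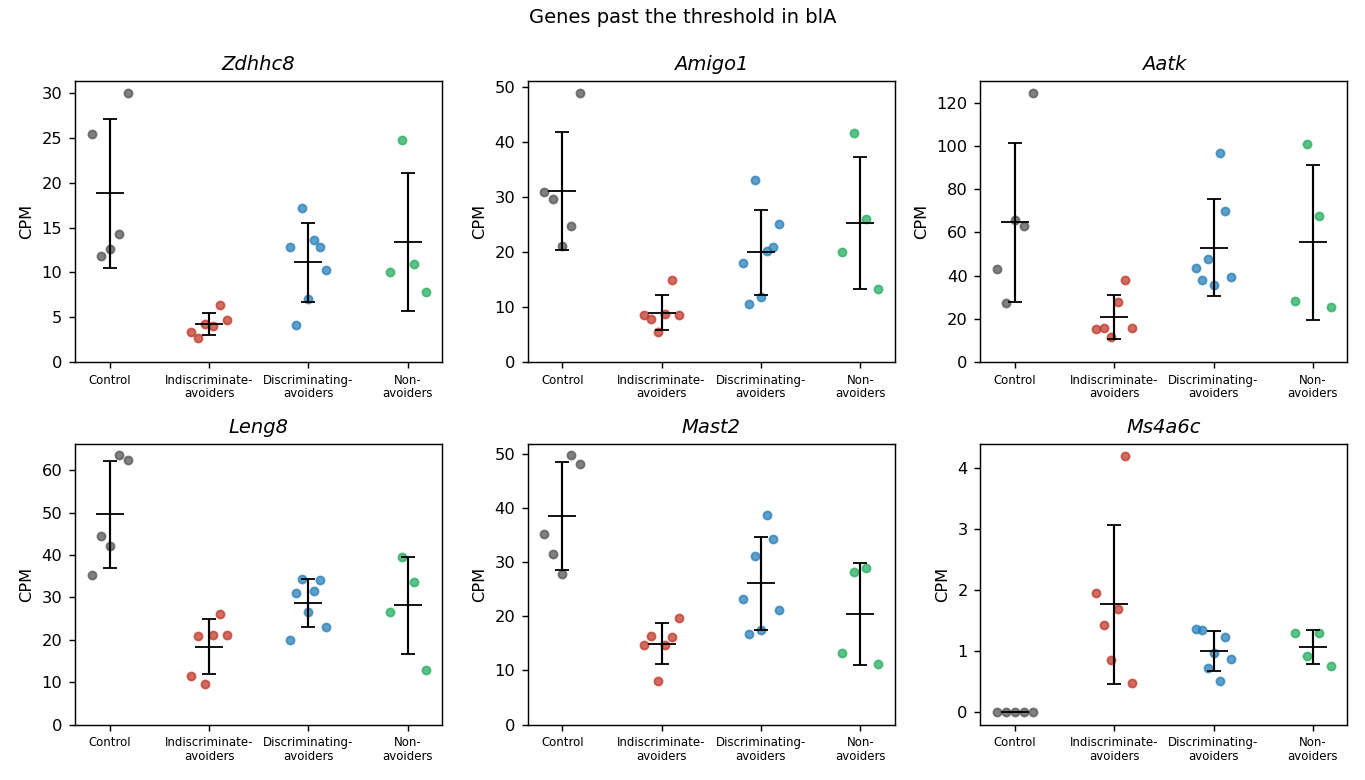
CPM per blA library of the 6 genes past the threshold, for Control (n = 5), Indiscriminate-avoiders (n = 6), Discriminating-avoiders (n = 7) and Non-avoiders (n = 4), with points for libraries and bars for the mean and SD. Ms4a6c is at 0 in the 5 Control libraries.

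Ms4a6c, a membrane protein of myeloid cells (chromosome 19, 11469366 to 11482192), had no count in the 5 Control libraries of the blA and 12 to 136 counts in each of the 17 defeated libraries. It stood at 1.76 ± 1.31 CPM (SD, n = 6) in Indiscriminate-avoiders, 0.997 ± 0.327 (n = 7) in Discriminating-avoiders and 1.07 ± 0.274 (n = 4) in Non-avoiders. Against a floor of 3 counts per library (0.117 CPM), these levels were at least 15.1-fold, 8.51-fold and 9.1-fold higher than in Controls. The adjusted p by edgeR was 0.00155, 0.00412 and 0.00554, and 0.00205 for all defeated mice against Controls. In Controls of the other regions Ms4a6c was present, at 1.09 ± 0.699 CPM (n = 6) in the vHC and 1.4 ± 1.55 CPM (n = 4) in the mPFC, where 1 of the 4 had no count. Over both regions 6 of 44 libraries had no count. Leaving out any 1 of the 22 blA libraries did not end these calls. They ended in Discriminating-avoiders and Non-avoiders with detected genes as a term (adjusted p 0.0693 and 0.144), in each of the 4 comparisons in set 2 alone, and in Indiscriminate-avoiders and Discriminating-avoiders in set 1 alone, while Non-avoiders, with 1 library in set 1, and all defeated mice were not tested there. Genes with a count averaged 22093 in blA Controls, the lowest of the 4 groups, with 18736 in library s50 and 21517 to 24351 in the others, and the erythrocyte list also had its lowest blA level there (4.61, against 6.7, 6.03 and 6.11 in Indiscriminate-avoiders, Discriminating-avoiders and Non-avoiders). Ms4a6c was the 1 gene called in the blA in Discriminating-avoiders, in Non-avoiders and in all defeated mice against Controls, beside 1413, 1050 and 2296 genes with an unadjusted p under 0.05. DESeq2 called 89 higher and 12 lower genes in Discriminating-avoiders, 62 genes in Non-avoiders and 235 in all defeated mice, and limma-voom 0 in each. In Discriminating-avoiders the count was 4 without Control library s53 or s101 and 2 without Discriminating-avoiders library s20, and in Non-avoiders it was 2 without Control library s53 or s101. In all defeated mice it was 6 without Control library s101, 3 without Control library s53 and 2 without Indiscriminate-avoiders library s86, Discriminating-avoiders library s20 or Non-avoiders library s74.

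Between the defeated phenotypes no gene passed in the blA. Psd, a neuronal exchange factor, stood at 174 ± 29 CPM (SD, n = 6) in Indiscriminate-avoiders and 441 ± 64.1 CPM (n = 7) in Discriminating-avoiders (adjusted p 0.0829), Arhgap33 at 14.3 ± 8.18 and 54.2 ± 20.8 CPM, and Mfsd12 at 4.57 ± 2.2 and 14.6 ± 2.96 CPM. Against Non-avoiders (46.9 ± 19.7 CPM, n = 4) Arhgap33 had an adjusted p of 0.656, and Ano1 and C2cd4c followed with 1.77 ± 1.75 and 0.816 ± 0.812 CPM in Non-avoiders. Between Discriminating-avoiders and Non-avoiders the smallest p were those of Avp (0.552 ± 1.14 against 6.47 ± 7.5 CPM), Nlrp1c-ps and Gh, at an adjusted p of 1. By edgeR 0 genes passed in each comparison, beside 2283 (Indiscriminate-avoiders against Discriminating-avoiders), 1660 (Indiscriminate-avoiders against Non-avoiders) and 176 (Discriminating-avoiders against Non-avoiders) with an unadjusted p under 0.05. DESeq2 called 216, 31 and 4 and limma-voom 233, 0 and 1. Indiscriminate-avoiders against Discriminating-avoiders gave 59 genes without Control library s98 and 3 without Non-avoiders library s83.

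No gene list passed in the blA (0 of 238 tests by fry, 34 with an unadjusted p under 0.05), while 4 tests passed without Indiscriminate-avoiders library s86 and 1 without Non-avoiders library s83. Of 12 microglial genes 3 rose in Indiscriminate-avoiders against Controls when adjusted over the list alone and 0 over all genes, and the level of the list was 6.03 ± 0.254 against 5.59 ± 0.102 (SD, n = 6 and 5, exact permutation p 0.00433, adjusted p 0.394 over 612 tests). That difference was 0.354 in set 1 and 0.515 in set 2, and 0.585 and 0.38 in pools 1 and 2. Other list levels differed in the same comparison: 6.7 against 4.61 for erythrocyte, 3.71 against 3.21 for mural and 2.74 against 2.31 for inflammatory genes. Glutamatergic genes were lower (3.15 against 4.08), and endothelial genes stood at 4.05 against 4.01. All 20 immediate early genes had values below 0 (median -0.567), with 0 past the test adjusted over the list alone and an adjusted p of 0.264 by fry. Glutamate receptor genes had a median of -0.722, and 1 of 22 fell adjusted over the list alone. Ribosomal protein genes lay above 0 in 39 of 39 members in Indiscriminate-avoiders against Non-avoiders (median 0.639, adjusted p 0.264). In the same comparison the nuclear-encoded respiratory chain list had a level of 9.14 ± 0.185 against 8.58 ± 0.456 (SD, n = 6 and 4, exact permutation p 0.0238, adjusted p 0.394). Across genes with a mean log2 CPM of at least 1, Spearman's rho of the log2 fold change was -0.364 with exonic length and -0.202 with GC content. In Indiscriminate-avoiders against Controls these rho were -0.287 and -0.28. Camera with a preset correlation called 47 of 238 tests, and with an estimated correlation it called 0, with a smallest adjusted p of 0.651.

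The blA libraries differed in their share of glutamatergic transcripts. Slc17a7, a vesicular glutamate transporter chosen after its values were seen, stood at 0, 19.6, 80.9, 230 and 783 CPM in Control libraries s98, s50, s53, s47 and s101. Its mean was 223 ± 326 CPM in Controls (SD, n = 5), 14.1 ± 17.1 in Indiscriminate-avoiders (n = 6), 172 ± 158 in Discriminating-avoiders (n = 7) and 66.7 ± 75.4 in Non-avoiders (n = 4), with an adjusted p of 0.247 for Indiscriminate-avoiders against Controls. The level of the glutamatergic list was 3.75 ± 1.31 over the 22 blA libraries, 4.66 ± 0.61 over the 25 vHC libraries and 5.5 ± 0.426 over the 19 mPFC libraries. Each level takes the members that passed the filter of its own region, so these levels are not strictly comparable.

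**Figure D3:**
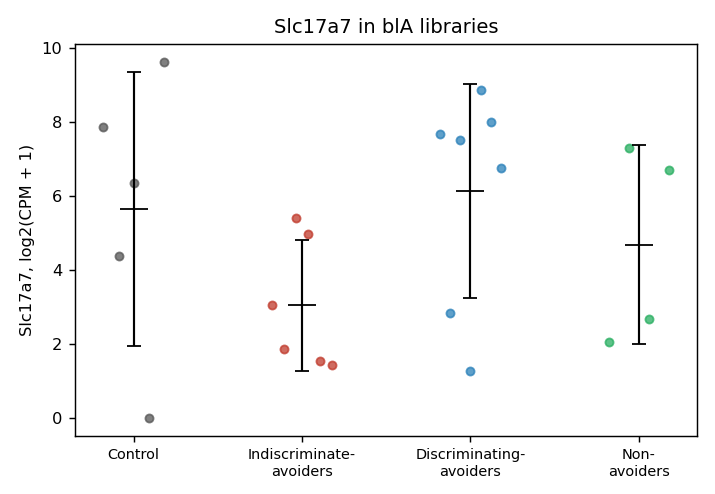
Slc17a7 in each blA library as log2(CPM + 1), with points for libraries and bars for the mean and SD in Control (n = 5), Indiscriminate-avoiders (n = 6), Discriminating-avoiders (n = 7) and Non-avoiders (n = 4). Control library s98 is at 0 CPM and Control library s101 at 783 CPM.

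In the vHC no gene passed in any of the 7 comparisons. Kpna6, a nuclear import factor, stood at 5.69 ± 1.08 CPM (SD, n = 5) in Discriminating-avoiders and 12.8 ± 5.2 CPM (n = 6) in Controls, and Sik3, a salt-inducible kinase, at 13.4 ± 2.51 and 29.8 ± 12.2 CPM, with adjusted p of 0.472 each. Ctla2a stood at 18.4 ± 6.58 and 7.86 ± 1.41 CPM. In Indiscriminate-avoiders the smallest p belonged to the haemoglobin genes Hbb-bs (511 ± 400 CPM, n = 7, against 116.5 ± 40.7) and Hba-a1 (214 ± 162 against 54.5 ± 16.9) and to Gulo, at an adjusted p of 1. In Non-avoiders they were Hspa5, an endoplasmic reticulum chaperone (449 ± 66.2 CPM, n = 7, against 684 ± 155), the clock output gene Dbp (61 ± 13.9 against 30.3 ± 10.7) and Pkdrej, also at an adjusted p of 1.

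Between Discriminating-avoiders and Non-avoiders of the vHC, Sik3 had a log2 value of -1.23 ± 0.24 (SE) and Pdzd7 one of -1.99 ± 0.395, both with an adjusted p of 0.432, and Kpna6 followed with -1.11 ± 0.24. Sult1a1, Hcrt and Sema3g had the smallest p between Indiscriminate-avoiders and Non-avoiders (adjusted p 1), and Adgrl2 (10.1 ± 4.57 against 1.41 ± 1.49 CPM, SD, n = 7 and 5), Kpna6 and Pdzd7 between Indiscriminate-avoiders and Discriminating-avoiders (adjusted p 0.928). Spon2, Ctla2a and Gulo led in all defeated mice (adjusted p 0.974). By edgeR 0 genes passed, beside 435, 2293, 301 and 784 with an unadjusted p under 0.05 in Indiscriminate-avoiders, Discriminating-avoiders, Non-avoiders and all defeated mice against Controls. DESeq2 called 10, 51, 5 and 5 genes there, and limma-voom 1, 0, 0 and 1. Among the phenotypes the unadjusted counts were 285 (Indiscriminate-avoiders against Non-avoiders), 1707 (Discriminating-avoiders against Non-avoiders) and 1018 (Indiscriminate-avoiders against Discriminating-avoiders), DESeq2 called 5, 34 and 28, and limma-voom 0 in each. All unadjusted counts but 2293 and 1707 lay below a share of 0.05 of the genes tested. Without Discriminating-avoiders library s72, 1 gene passed between Discriminating-avoiders and Non-avoiders.

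Of the gene lists in the vHC, 0 of 238 tests passed by fry (25 with an unadjusted p under 0.05), and 2 passed without Discriminating-avoiders library s72. Monoamine receptor genes lay below 0 in 15 of 15 members in Discriminating-avoiders against Controls (median -0.951), among them Adra2a (-1.51) and Htr2c (-1.20), with 0 past the test adjusted over the list alone and an adjusted p of 0.334. The list level differed by -0.815 (exact permutation p 0.00866, adjusted p 0.394 over 612 tests, n = 5 and 6), with -0.937 in set 1, -0.655 in set 2 and -1.34 in pool 1, while pool 2 held no Controls. Genes with a count averaged 23239 in these Discriminating-avoiders, with 19671 in library s18, and 25155 in Controls (exact permutation p 0.0563, adjusted p 0.744). Without library s18 the smallest adjusted p of any vHC list by fry was 0.512. In the same comparison the striatal-type level was 2.66 ± 0.565 against 3.68 ± 0.934 (SD, exact permutation p 0.0433, adjusted p 0.448) and the choroid plexus level 2.82 ± 2.05 against 5.62 ± 1.84 (exact permutation p 0.0498, adjusted p 0.448). Of 12 striatal-type genes 5 fell in Discriminating-avoiders against Non-avoiders adjusted over the list alone and 0 over all genes (median -2.44, adjusted p 0.431 by fry). Ependymal genes lay below 0 in 8 of 8 members in Non-avoiders against Controls (median -1.13, adjusted p 0.431 by fry), at a level of 2.91 ± 1.32 against 4.29 ± 0.794 (SD, n = 7 and 6, exact permutation p 0.0565, adjusted p 0.457), and the choroid plexus level in the same comparison was 3.59 ± 2.34 against 5.62 ± 1.84 (exact permutation p 0.108, adjusted p 0.554). Camera called 62 of 238 tests with a preset correlation and 0 with an estimated one, where the smallest adjusted p was 0.0747.

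In the mPFC no gene passed either. Tmed9, a cargo receptor of the secretory pathway, stood at 342 ± 118 CPM (SD, n = 5) in Non-avoiders and 126 ± 15.3 CPM (n = 4) in Controls (adjusted p 0.073), and Aen and Kcnmb1 followed at an adjusted p of 1. In Indiscriminate-avoiders against Controls the smallest p were those of the lysosomal protease Ctsc (98.5 ± 74.4 CPM, n = 6, against 22.8 ± 11) and Hba-a1 (873 ± 778 against 133 ± 72.3), and in Discriminating-avoiders those of Fam83c, Vmn1r4 and Hpx, with an adjusted p of 1 in each. Between Indiscriminate-avoiders and Non-avoiders Tmed9 (149 ± 24.9 against 342 ± 118 CPM) had an adjusted p of 0.376, and Fxyd5 (59.1 ± 28.2 against 15.2 ± 3.3 CPM) and Kcnmb1 came next. Serping1, a complement inhibitor (71.6 ± 54.5 against 7.69 ± 4.45 CPM, n = 6 and 4), Fxyd5 and the transporter Slc22a8 (90 ± 57.1 against 16.7 ± 8.26 CPM) led between Indiscriminate-avoiders and Discriminating-avoiders, Tmed9, Tacr1 and Kcnmb1 between Discriminating-avoiders and Non-avoiders, and Tnfrsf25 and Tmed9 in all defeated mice.

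By edgeR 0 genes passed in the mPFC, beside 931, 525, 1017 and 917 with an unadjusted p under 0.05 in Indiscriminate-avoiders, Discriminating-avoiders, Non-avoiders and all defeated mice against Controls. DESeq2 called 109, 137, 120 and 91 genes there and limma-voom 0, 1, 1 and 0. Among the phenotypes the unadjusted counts were 1029 (Indiscriminate-avoiders against Non-avoiders), 520 (Discriminating-avoiders against Non-avoiders) and 816 (Indiscriminate-avoiders against Discriminating-avoiders), with 81 higher and 24 lower, 116 and 166 genes by DESeq2 and 1, 1 and 2 by limma-voom. Every unadjusted count in the mPFC lay below a share of 0.05 of the genes tested. Of the gene lists 0 of 238 tests passed by fry, beside 21 with an unadjusted p under 0.05. Of 9 meningeal fibroblast genes 5 rose in Indiscriminate-avoiders against Discriminating-avoiders adjusted over the list alone and 0 over all genes (median 3.38, adjusted p 0.51), and the level of the list was 4.51 ± 1.28 against 2.01 ± 0.669 (SD, n = 6 and 4, exact permutation p 0.0238, adjusted p 0.394 over 612 tests). That difference was 2.17 in set 1, where Discriminating-avoiders have 1 library, 2.54 in set 2, and 2.57 and 2.36 in pools 1 and 2. In the same comparison the levels were 4.09 against 3.01 for mural, 4.61 against 3.91 for endothelial, 8.53 against 6.17 for erythrocyte and 3.44 against 2.69 for inflammatory genes (exact permutation p 0.0238, 0.0381, 0.0238 and 0.0857, adjusted p 0.394, 0.448, 0.394 and 0.547). Camera called 39 of 238 tests with a preset correlation and 0 with an estimated one, where the smallest adjusted p was 0.283.

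Erythrocyte transcripts had higher levels in Indiscriminate-avoiders than in Controls in each region. The 3 regions were punched largely from the same animals, so they are not independent results, and neither are the 5 genes of the list. The level of the 5-gene list was 6.7 ± 0.81 against 4.61 ± 0.856 in the blA (SD, n = 6 and 5), 6.98 ± 1.12 against 5.31 ± 0.39 in the vHC (n = 7 and 6) and 8.53 ± 1.45 against 6.03 ± 1.24 in the mPFC (n = 6 and 4). Hbb-bs, a beta-globin gene, stood at 354 ± 175 against 81.5 ± 64.7 CPM in the blA and 1647 ± 1520 against 270 ± 181 CPM in the mPFC. Adjusted over the list alone, 5 of 5 genes rose in each region, and 0 over all genes. The level differences were 2.09, 1.68 and 2.5 in blA, vHC and mPFC, with exact permutation p of 0.0108, 0.00408 and 0.0238, and an adjusted p of 0.394 each over 612 tests, of which 67 had an unadjusted p under 0.05. By fry the adjusted p was 0.109, 0.334 and 0.51, and with an estimated correlation camera gave adjusted p of 0.651, 0.0747 and 0.283.

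Within sets 1 and 2 the erythrocyte differences were 2.17 and 1.87 in the blA, 0.975 and 2.17 in the vHC and 3.75 and 1.43 in the mPFC. Within pools 1 and 2 they were 2.97 and 1.62 in the blA and 2.09 and 2.79 in the mPFC, and in the vHC 2.21 in pool 1, while pool 2 held no Controls. In the mPFC the exact permutation p was 0.0714 without Control library s52. Discriminating-avoiders had erythrocyte levels of 6.03 ± 0.475 in the blA (n = 7), 6.4 ± 0.949 in the vHC (n = 5) and 6.17 ± 1.1 in the mPFC (n = 4), and Non-avoiders 6.11 ± 1.05 (n = 4), 6.16 ± 0.594 (n = 7) and 6.68 ± 0.804 (n = 5).

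**Figure D4:**
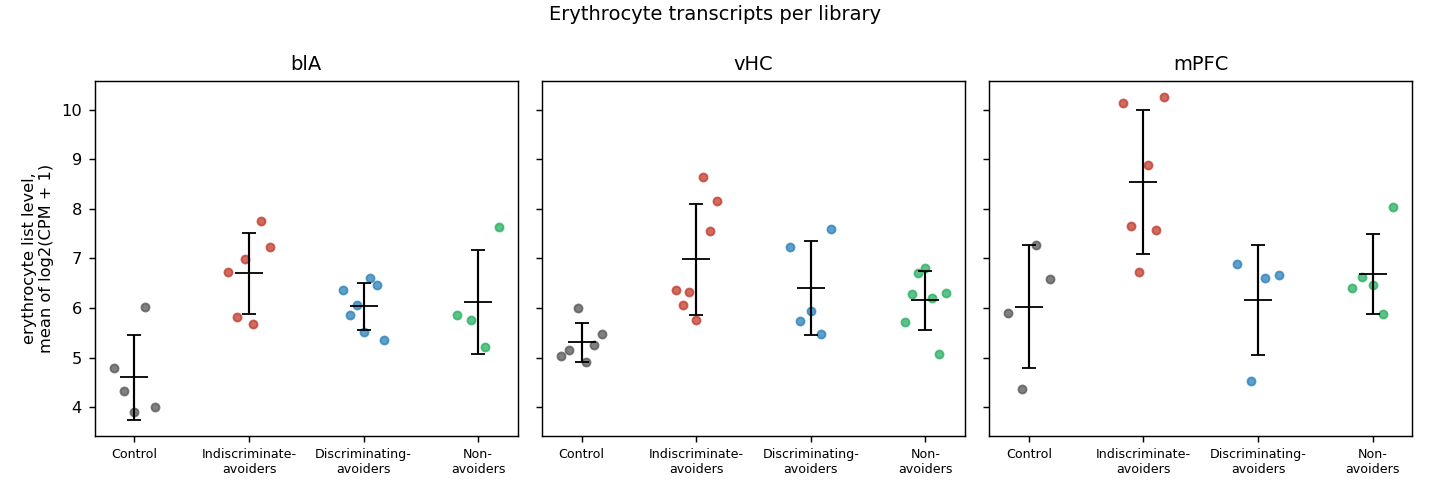
Level of the erythrocyte list per library, as the mean of log2(CPM + 1) over 5 genes, by phenotype in blA, vHC and mPFC, with points for libraries and bars for the mean and SD. Indiscriminate-avoiders average 6.7, 6.98 and 8.53 and Controls 4.61, 5.31 and 6.03.

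Genes of the stress response and of neuronal activity did not pass in any comparison of phenotypes within a region. In the blA of Indiscriminate-avoiders against Controls, Sgk1, a glucocorticoid-induced kinase, had a log2 value of 1.13 ± 0.464 (SE, adjusted p 0.262), the activity-dependent factor Npas4 one of -2.05 ± 0.765 (adjusted p 0.215), Crh one of 1.11 ± 0.51 (adjusted p 0.32) and Arc one of -0.63 ± 0.3. Ttr, a choroid plexus marker, had a value of 4.31 ± 1.48 (adjusted p 0.176) in that comparison. It was scarce in the blA, at 4.57 ± 9.41 CPM (SD, n = 22), against 3230 ± 3540 CPM in the vHC (n = 25). In all defeated mice against Controls of the blA the values were -0.09 ± 0.396 for Fkbp5, a co-chaperone of the glucocorticoid receptor, -0.04 ± 0.159 for the receptor gene Nr3c1, -0.44 ± 0.314 for Fos and -0.51 ± 0.877 for Bdnf. Tsc22d3, another glucocorticoid target, had a value of 0.26 ± 0.126 in the vHC (adjusted p 0.974).

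The change from Control was then compared between regions. In Indiscriminate-avoiders it differed for 1 gene, Osbpl9, which encodes a lipid transfer protein (chromosome 4, 109061145 to 109202272, adjusted p 0.0491 by edgeR's quasi-likelihood F-test). Its level was 95.8 ± 36.8 CPM against 68.8 ± 38.7 in Controls in the blA (SD, n = 6 and 5), 79.8 ± 18.7 against 84 ± 18.9 in the vHC (n = 7 and 6) and 74.9 ± 30.1 against 43.7 ± 13.1 in the mPFC (n = 6 and 4). With no low-count filter 0 genes passed, and limma-voom with the animal as a random effect also called 0. In Discriminating-avoiders, Non-avoiders and all defeated mice edgeR called 0 genes, beside 1984, 1198 and 1646 with an unadjusted p under 0.05, and limma-voom called 2, 15 and 3. DESeq2 was not run on this model.

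The log2 differences between defeated and Control mice were compared between the 2 sets of animals across genes, which are not independent replicates. Pearson's r was 0.155 in the blA, 0.144 in the vHC and 0.0813 in the mPFC. Of 100 permutations of the phenotype labels 7, 13 and 12 gave an r as high, for one-sided permutation p of 0.079, 0.14 and 0.13. In the blA r was 0.0978 without Control library s101. In the vHC it was -0.0308 without Control library s51, 0.223 without Control library s45 and 0.0574 without Non-avoiders library s27. In the mPFC it was -0.0949 without Control library s103, -0.0229 without Control library s49, 0.15 without Control library s52 and 0.151 without Control library s97.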

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

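Chosen after the results were seen were the tests of library s98, of vessel tissue, of 1 library with much blood, of microglia and of a strain or colony variant, while the tests of GC content and length, of blood content of the animal, of paralogs and of drop-out were set before their results were seen. For drop-out the share of splits lay under the preset bound of 0.05, which went against it. It was left open only after that value was seen, because libraries of other regions also lacked a count. The erythrocyte level of library s64, from the mPFC of Discriminating-avoiders, was 4.52, against a median of 6.66 in the other libraries of its group. Amigo1 stood at 14.9 CPM in library s89, from the blA of Indiscriminate-avoiders, against a median of 8.43 in the others. These were the 2 values past Dixon's limit in 95 tests, where chance passes about 1 in 20. Osbpl9 changed differently between regions in Indiscriminate-avoiders against Controls, with an adjusted p of 0.0491.

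Zdhhc8, Amigo1, Aatk, Leng8 and Mast2 were lower in the blA of Indiscriminate-avoiders than of Controls. Control library s98 had no Slc17a7 count and may come from other tissue, but without it the median log2 fold change of the 5 genes was -1.86, so this library alone does not account for them. For Zdhhc8, Amigo1, Leng8 and Mast2 every Indiscriminate-avoiders library lay below every Control library, so leaving out 1 Control could not remove their difference. Slc17a7 was also low in Indiscriminate-avoiders (1.67 to 40.8 CPM, against 0 to 783 in Controls), which leaving out s98 does not address. Transcript GC content and length may contribute: with each library corrected for its trend, the median moved from -1.73 to -1.24, within the spread of a value of -1, and 4 of the 5 calls ended, at adjusted p of 0.0965 to 0.138, with each fold closer to 0, while what else ended them was not tested. Aatk went from -1.73 ± 0.296 (SE) to -1.08 ± 0.174 and stayed past the threshold, while Zdhhc8 went from -2.21 ± 0.363 to -1.62 ± 0.321, Amigo1 from -1.83 ± 0.321 to -1.56 ± 0.282, Mast2 from -1.39 ± 0.242 to -1.24 ± 0.246 and Leng8 from -1.49 ± 0.254 to -1.10 ± 0.242. A defeat effect and differences in the tissue punched stay open.

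Erythrocyte transcripts were higher in Indiscriminate-avoiders than in Controls in the 3 regions, which were punched largely from the same animals. If more vessel tissue were the source, endothelial genes would be higher too: their difference was 0.0212, 0.0463 and 0.21 of the erythrocyte difference in blA, vHC and mPFC, mural levels differed by 0.499, 0.115 and 0.593 and meningeal levels by 0.285, -0.398 and 1.54, which argues against vessel tissue in the vHC (endothelial 0.0776 ± 0.167, mural 0.115 ± 0.186, SE, against 1.68) and leaves it open in blA and mPFC. If 1 library per region with much blood were the source, the difference without it would be under 0.5 in at least 2 regions, but it was 1.88 ± 0.494, 1.4 ± 0.415 and 2.16 ± 0.856 (SE), above 0.5 by more than its SE in each region, so such a library does not account for the pattern, although 1.4 lies within its SE of a stricter bound of 1. Blood content of the animal is a candidate explanation but rests on few animals: deviations from the group means correlated between blA and vHC of the same animals (Pearson r 0.551, permutation p 0.0173, adjusted p 0.026, Spearman rho 0.534, p 0.0247, adjusted p 0.0685, n = 18, r 0.527 without the 2 farthest animals, 0.336 in set 1 and 0.618 in set 2). Of the 3 region pairs tested, r was 0.635 between blA and mPFC (rho 0.547, permutation p 0.0159 and 0.0457, n = 14) and 0.427 between vHC and mPFC (rho 0.377, permutation p 0.0874 and 0.137, n = 17), these fell to 0.452 and 0.309 without the 2 farthest animals, and within sets 1 and 2 they were 0.269 (n = 6) and 0.9 (n = 8), and -0.09 (n = 8) and 0.655 (n = 9).

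Ms4a6c had no count in the 5 blA Controls. If its reads had gone to Ms4a6b or Ms4a6d, these would be higher in Controls, but their summed level was lower by 4.08 CPM (difference -4.08, 4.16 ± 1.83 against 8.24 ± 4.42 CPM, SD, permutation p 0.0354). Fewer microglia in Controls would lower the microglial list about as much, but its median log2 fold change was 0.373, and a strain or colony variant would leave these animals without the gene elsewhere, but 5 of the 5 had it above 3 counts in their vHC or mPFC library (4 to 90 counts in the libraries with any). Drop-out of scarce transcripts stays open: a share of 0.0193 (509 of 26334 splits into 5 and 17) held such a gene, and Controls s53 and s101 had none with 23821 and 24351 detected genes, more than the 21459 and 21706 of Indiscriminate-avoiders s86 and s38, which had counts, but the splits take all libraries as equally liable and 6 of 44 vHC and mPFC libraries had no count either. Fewer myeloid cells of the blood also stay open, since the erythrocyte level was lowest in Controls (4.61, against 6.7, 6.03 and 6.11) and Ms4a6b and Ms4a6d were lower there too, and so does an effect of defeat.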

How the results depend on the processing

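Chosen after the data were seen were the pool term, leaving out libraries with fewer than 20000 genes, the term for detected genes, the stricter filter, the correction for GC content and length and the scaling by total counts. No value of a named gene past the threshold changed direction under an alternative. Of the values counted as past the threshold, 341 were no longer past it under an alternative, against 699 that were. These counts also hold refits of the erythrocyte list level in Indiscriminate-avoiders against Controls. That level counted as past the threshold by its unadjusted permutation p, although it did not pass after adjustment. Of values not past the threshold, 8622 stayed so, 456 of them with a change of sign, and 46 passed. In the blA, Indiscriminate-avoiders against Control gave 1 gene with no set term, with a pool term, with detected genes as a term or without library s26, 0 in set 1 or set 2 alone, 3 with GC content and length as offsets, 19 without libraries under 20000 genes, 75 with the stricter filter, 34 by limma-voom and 825 by DESeq2. With fewer genes tested the adjustment can be milder, which was not tested apart from the refit. Ms4a6c is removed by the stricter filter, so Discriminating-avoiders, Non-avoiders and all defeated mice against Control gave 0 there. By limma-voom these also gave 0, in set 2 alone 0, and with detected genes as a term 0 for the first 2. Discriminating-avoiders gave 0 in set 1 alone, all defeated mice gave 2 with a pool term, and Indiscriminate-avoiders against Discriminating-avoiders gave 5 with the stricter filter. DESeq2, in the order Indiscriminate-avoiders, Discriminating-avoiders, Non-avoiders and all defeated mice against Control, then Indiscriminate-avoiders against Non-avoiders, Discriminating-avoiders against Non-avoiders and Indiscriminate-avoiders against Discriminating-avoiders, gave 825, 1.0e+02 (rounded, 89 higher and 12 lower), 62, 235, 31, 4 and 216 in the blA, 10, 51, 5, 5, 5, 34 and 28 in the vHC, and 109, 137, 120, 91, 1.1e+02 (rounded, 81 higher and 24 lower), 116 and 166 in the mPFC. In the same order limma-voom gave 34, 0, 0, 0, 0, 1 and 233, then 1, 0, 0, 1, 0, 0 and 0, then 0, 1, 1, 0, 1, 1 and 2. Except for the removal of Ms4a6c by the stricter filter, the cause of these changes was not tested. Control libraries only gave 82, 12 and 5 genes for vHC against mPFC, blA against mPFC and vHC against blA, with fewer samples. The region difference gave 0 genes with no low-count filter in Indiscriminate-avoiders, and limma-voom with the animal as a random effect gave 0, 2, 15 and 3. Camera with a preset correlation gave 47, 62 and 39 list tests in blA, vHC and mPFC, and with an estimated correlation 0 in each. Leaving out 1 library at a time gave 1 to 301 genes in Indiscriminate-avoiders, 1 to 4 in Discriminating-avoiders, 1 to 2 in Non-avoiders and 1 to 6 in all defeated mice against Control in the blA, and 0 to 59 between Indiscriminate-avoiders and Discriminating-avoiders. It gave 0 to 1 in the vHC between Discriminating-avoiders and Non-avoiders, 0 to 4 list tests in the blA and 0 to 2 in the vHC, and r between sets of 0.0978 to 0.187 in the blA, -0.0308 to 0.223 in the vHC and -0.0949 to 0.151 in the mPFC. Leaving out each animal in turn from the region difference was not run. Phenotypes within a region could not be paired, because the groups of a region came from different animals by the animal codes. The comparisons between regions used the animal as a block. In simulated libraries of Indiscriminate-avoiders and Control edgeR recovered 20%, 42% and 3% of genes changed 2-fold in blA, vHC and mPFC.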

Other observations

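The counts of other splits of the samples were chosen after the results were seen, and so were the comparisons of list levels given here as values. In the blA the choroid plexus list had 3 members that rose in Indiscriminate-avoiders against Controls adjusted over the list alone and 0 over all genes (median 0.651), and oligodendrocyte genes had 4 that rose against Discriminating-avoiders adjusted over the list alone and 0 over all genes (median 0.792, adjusted p 0.372 by fry). The microglial list level was also higher in Discriminating-avoiders than in Controls of the blA, by 0.316 (exact permutation p 0.00505, adjusted p 0.394 over 612 tests). Erythrocyte (6.03 against 4.61) and mural levels (3.54 against 3.21) were higher there too, while the glutamatergic level was 4.13 against 4.08. Genes with a count averaged 24579 in these Discriminating-avoiders and 22093 in Controls. In the vHC 12 of 12 microglial genes lay above 0 in Indiscriminate-avoiders against Controls (median 0.39, adjusted p 0.431). Choroid plexus levels in the vHC averaged 4.0 ± 2.25 (SD, n = 25), against 1.2 ± 0.272 in the blA (n = 22), where each level takes the members that passed its own region's filter. In the vHC these levels differed by -2.79 between Discriminating-avoiders and Controls (exact permutation p 0.0498, adjusted p 0.448).

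For each comparison within a region, 40 splits of the samples into groups of the same sizes were drawn, the real one included. In the blA, Indiscriminate-avoiders against Controls gave 6 genes, the highest other split gave 2, and 1 of 40 gave as many. This is the smallest share that 40 splits allow, and it was not adjusted over the 21 comparisons, so it does not exclude chance over all of them. At an unadjusted p under 0.05 this comparison gave 3251 genes, another split gave 3323, and 2 of 40 gave as many, so chance is not excluded by that count either. The count of 6 was 1 with a pool term and 1 without any 1 of 12 of the 22 libraries. Discriminating-avoiders against Controls gave 1 gene against 0 in the highest other split (1 of 40), while 8 of 40 gave as many at an unadjusted p under 0.05 (1413 genes, at most 2920 in another split). Non-avoiders against Controls gave 1 gene against 2 in the highest other split, and 2 of 40 gave as many, a share at the limit of 0.05, so chance is not excluded there. The number of splits had been lowered from 50 to 40 after a first run was seen, in which this share lay under 0.05, so this verdict depends on the number drawn. All defeated mice gave 1 gene against 2 (3 of 40), and chance is not excluded. In the other 17 comparisons within a region the real count was 0, so 40 of 40 splits gave as many by construction, and the highest other split gave 0 in the 3 comparisons among defeated mice of the blA, at most 1 in the vHC and at most 3 in the mPFC. At an unadjusted p under 0.05, 32, 2, 36 and 13 of 40 splits gave as many in the vHC. In the mPFC 13, 28, 16 and 14 did. The order is Indiscriminate-avoiders, Discriminating-avoiders, Non-avoiders and all defeated mice against Controls. For Indiscriminate-avoiders against Non-avoiders, Discriminating-avoiders against Non-avoiders and Indiscriminate-avoiders against Discriminating-avoiders, 37, 3 and 8 did in the vHC and 7, 31 and 17 in the mPFC.

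For the regions 50 splits were drawn and refitted with limma-voom. Region labels gave 1219 genes between vHC and mPFC, 736 between blA and mPFC and 325 between vHC and blA, against 1, 0 and 0 in the highest other split (1 of 50 each). This is the smallest share that 50 splits allow, but no other split came near the real counts. The counts of edgeR's glmTreat were not refitted on other splits. The difference of a phenotype's change between regions gave 0, 2, 15 and 3 genes for Indiscriminate-avoiders, Discriminating-avoiders, Non-avoiders and all defeated mice, while 50, 20, 9 and 19 of 50 splits gave as many and the highest other splits gave 171, 161, 84 and 597, so chance is not excluded for the last 3. For Indiscriminate-avoiders a real count of 0 fixes that share, and the call of Osbpl9 by edgeR was not refitted on other splits. Why some splits called several times the real count was not tested.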
